A study of Arabidopsis thaliana with 12 samples.

How the data were processed

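The values were the authors' deposited intensities, a single value table of 3439 probes by 12 samples, 6 WT and 6 psad1, all of total RNA from *Arabidopsis thaliana* Columbia 0 per the labels. The unit was taken from the values: they are never negative, strongly skewed and on a linear scale. The array's scanner, background correction and scaling are not given in the sources used here, nor are the tissue, the age of the plants and the growth conditions. Column means of the deposited intensity agreed within 5% (1.05 to 1.07), so the table counted as normalized between samples and was used as deposited. The median intensities of WT samples 1 to 6 were 0.589, 0.591, 0.593, 0.599, 0.583 and 0.576, and those of psad1 samples 1 to 6 were 0.554, 0.561, 0.596, 0.608, 0.616 and 0.623. Between 139 and 160 probes per sample were listed at 0, and 123 in all samples. The highest value was exactly 100 in 4 samples, all psad1, and whether this is a ceiling is unknown. Tests compared samples within a probe, since levels of different probes are not comparable.

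Intensities below a floor, the 5th percentile of the positive values of each sample (0.152 to 0.184), were set to the floor and log2 was taken. The 237 probes at or below the floor in all 12 samples were left out, and 3202 were tested. A fold change near the floor is understated. Log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg over all tested probes, threshold 0.05). Figures were drawn with matplotlib 3.10.9.

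Genes were named from the platform's probe annotation, with symbols updated through the gene table of assembly TAIR10.1, in which 690 of 692 single-gene probes were matched. Of the 3439 probes, 692 had 1 gene, 870 had several and 1877 were not listed. A gene was named only from a probe with 1 gene. The array's own build is not given in the sources used here, so no coordinates are printed. PSAD1 and PSAD2 were to be tested first as a check of the labels, but no probe with 1 or several genes listed them, so these tests gave no value.

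The tests, the rule for named genes, 22 gene lists of 338 genes and most alternatives were fixed before the data were examined. Named genes were the 10 largest increases and the 10 largest decreases on the log2 scale among probes with exactly 1 gene past the threshold, plus PSAD1 and PSAD2 and up to 4 members with the smallest p of each list with at least 3 measured genes. Lists of that size were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. For every list the members that rose, fell or did not pass were counted, over all probes and adjusted over the list alone.

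The design treated the 12 samples as independent. Deviations from the genotype means showed sets of 2 samples in each genotype (numbers 1 and 2, 3 and 4, 5 and 6), with a consensus correlation of 0.727 within sets. The alternative set for this case was therefore run for every test: the 3 set averages per genotype as replicates, and the sets as a random block. Nothing in the labels says that samples or sets came from separate plants, so p-values measure the spread between samples, which may be technical. Named log2 changes do not depend on this choice, and the SE printed is that of set averages. With 3 sets against 3, an exact permutation test cannot give a p under 0.1, and calls on set averages rest on limma's shared variance.

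The tests were tried on simulated data with the measured set structure, in which 200 of 3202 probes were changed. At a log2 change of 1 the set averages recovered 91% and the 12 samples 100%, and at 0.5 they recovered 46% and 88%. False calls made up 2.84% of calls on set averages and 39.5% on 12 samples. Set differences were simulated separately for each probe, whereas neighbouring probes shared them in the data, so these percentages need not hold there. Other alternatives were quantile normalization, median centring, a 10th percentile or common floor, an offset, a filter on dim probes, the sample number as a block, a trend and robust fit, Welch's test for each probe, array weights, other thresholds and leaving out each sample or set. A position correction was added after the data were seen: from each sample's deviations from the probe means, the running median over 25 neighbouring probe numbers was subtracted.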

Results

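Total RNA of the *Arabidopsis thaliana* ecotype Columbia 0 was profiled on an array of 3439 probes, in 6 wild-type (WT) samples and 6 samples of the psad1 mutant. The mutant lacks PSI-D1, a form of the PSI-D subunit on the stromal side of photosystem I, the complex that passes electrons to ferredoxin in the chloroplast. The comparison asks how transcript levels differ when this protein is missing. Mean intensity per sample lay between 1.05 and 1.07 and median intensity between 0.554 and 0.623. The 10 brightest probes held between 13.7% and 15.4% of a sample's summed intensity. The number of samples limits the precision of every value.

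The 12 samples were not 12 independent measurements. Within each genotype, samples 1 and 2, samples 3 and 4, and samples 5 and 6 resembled each other far more than the rest. Across probes, the deviations of such partners from their genotype's mean correlated with r between 0.469 and 0.649, against −0.609 to −0.11 for samples of different sets. For 12 of 12 samples the closest sample of the same genotype was the partner. For genes that passed, the outcome is therefore given on all 12 samples and on the 3 set averages per genotype. Means ± SD refer to 3 set averages. List tests are on 12 samples where no fit is named. The first principal component, with 34.1% of the variance, separated psad1 from WT.

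**Figure D1:**
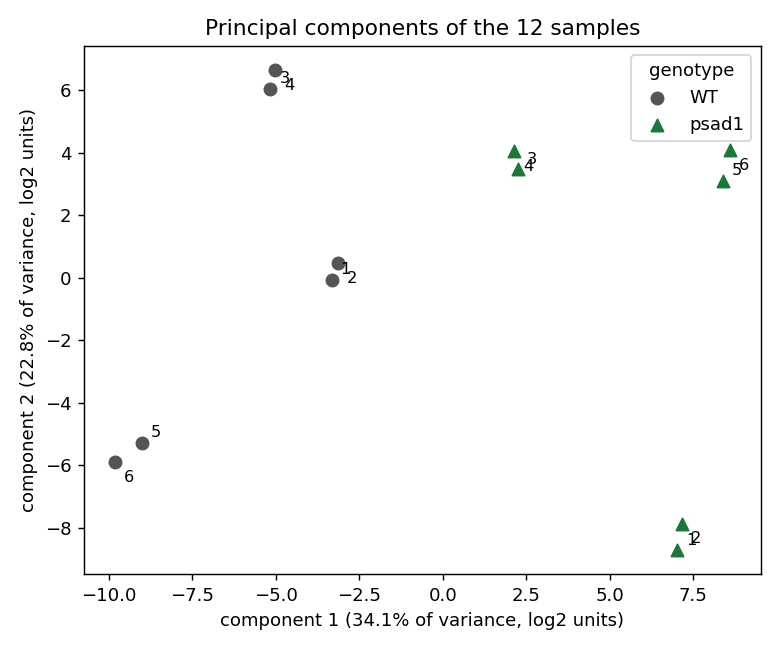
Principal components of log2 intensities of the 12 samples, each point a sample marked with its number within the genotype. Component 1 (34.1% of the variance) separates psad1 from WT, and samples lie close together as sets of 2.

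Among genes named by a probe of their own, CCL, a CCR-like gene known for a clock-regulated and unstable transcript, fell in psad1. Its intensity was 7.45 ± 0.387 (SD, n = 3) in WT and 4.57 ± 0.289 in psad1, a log2 change of −0.71 with a standard error (SE) of 0.10. AT1G06730, which encodes a pfkB-type carbohydrate kinase, rose from 0.424 ± 0.0193 to 0.657 ± 0.0626, by 0.63 on the log2 scale (SE 0.11). AT4G32060, which encodes the mitochondrial calcium uptake protein MICU, rose from 2.11 ± 0.0264 to 2.98 ± 0.114, by 0.50 (SE 0.10). In these 3 genes every psad1 set average lay outside the range of the WT set averages. They were picked because they passed on set averages, which makes this likely. With limma the adjusted p was 4.2e-06 for CCL, 3.5e-05 for AT1G06730 and 3.5e-05 for AT4G32060 on 12 samples, and 0.0113, 0.0282 and 0.0479 on set averages. With a set left out these rose to as much as 0.0823, 0.129 and 0.196, and none of the 3 genes passed on set averages without WT set 1, WT set 2 or psad1 set 2. Without WT set 3 or psad1 set 1 only CCL passed, and without psad1 set 3 CCL and AT1G06730 did. AT4G32060 passed with no set left out only. On set averages with the set number as a block, CCL (0.0274) and AT1G06730 (0.0396) passed and AT4G32060 (0.0648) did not.

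The other increases named here were between 1.41-fold and 1.51-fold and passed the test on 12 samples but not on set averages. PAC (AT2G48120), known as PALE CRESS and needed for chloroplast development, measured 0.606 ± 0.126 in psad1 against 0.418 ± 0.0556 in WT (log2 change 0.53, SE 0.16, adjusted p 0.00803 on 12 samples and 0.163 on set averages). AT4G39690, which encodes the MIC60 subunit of the complex that shapes mitochondrial cristae, measured 2.70 ± 0.297 against 1.85 ± 0.2 (log2 change 0.54, SE 0.13, adjusted p 0.000769 and 0.0789). AT1G01250, a transcription factor gene of the DREB group, changed by 0.54 on the log2 scale with an adjusted p of 0.0171 and 0.216. AT4G17070 measured 25 ± 0.205 in psad1 against 17 ± 2.32 in WT (log2 change 0.56, SE 0.12, adjusted p 0.000373 and 0.055). AT4G33540, AT1G24040, AT2G26110 and AT3G52550 had log2 changes of 0.60, 0.58, 0.57 and 0.50. Without the set of psad1 samples 5 and 6 the log2 change was 0.25 for AT3G52550 and 0.34 for AT1G01250. In all 10 named increases, AT1G06730 and AT4G32060 included, each psad1 set average was above each WT set average. Picking genes by size and p from these same data makes this likely, so it is no separate support.

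Of the 10 named decreases, CSLA01 (AT4G16590), a cellulose synthase-like gene of the glucomannan synthase family, came closest to CCL in its test. It measured 0.295 ± 0.04 in psad1 and 0.45 ± 0.0322 in WT (log2 change −0.62, SE 0.12), with an adjusted p of 0.000294 on 12 samples and 0.0505 on set averages. AT-HF (AT4G26900), a gene of histidine synthesis, had a log2 change of −0.49 (SE 0.14, adjusted p 0.00453 and 0.157). AT1G68660, which encodes the CLPS1 adaptor of the chloroplast Clp protease, had a log2 change of −0.46 (SE 0.11, adjusted p 0.000599 and 0.0833). The log2 change was −0.73 for AT2G11270, −0.65 for AT5G05330, −0.57 for AT4G03150, −0.55 for AT3G09080, −0.52 for AT4G18180 and −0.42 for AT1G35510, all past the threshold on 12 samples but not on set averages. With the set number as a block on set averages, limma's adjusted p was 0.0432 for CSLA01, 0.0472 for AT2G11270, 0.0354 for AT5G05330 and 0.0478 for AT4G03150. That fit was chosen after the data were seen, and the numbers were not taken to pair the samples. AT5G05330 was at the intensity floor in 2 of 6 psad1 samples, so its decrease is understated. With the floor at the 10th percentile the log2 change was −0.40 for AT5G05330 and −0.36 for AT4G03150, and with an offset in place of a floor −0.41 and −0.29, and −0.37 for CSLA01, all past the threshold on 12 samples. Each psad1 set average was below each WT set average in 9 of the 10 decreases, the exception being AT2G11270 with 2 of 3 psad1 sets below. The way the genes were picked makes this likely here too.

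**Figure D2:**
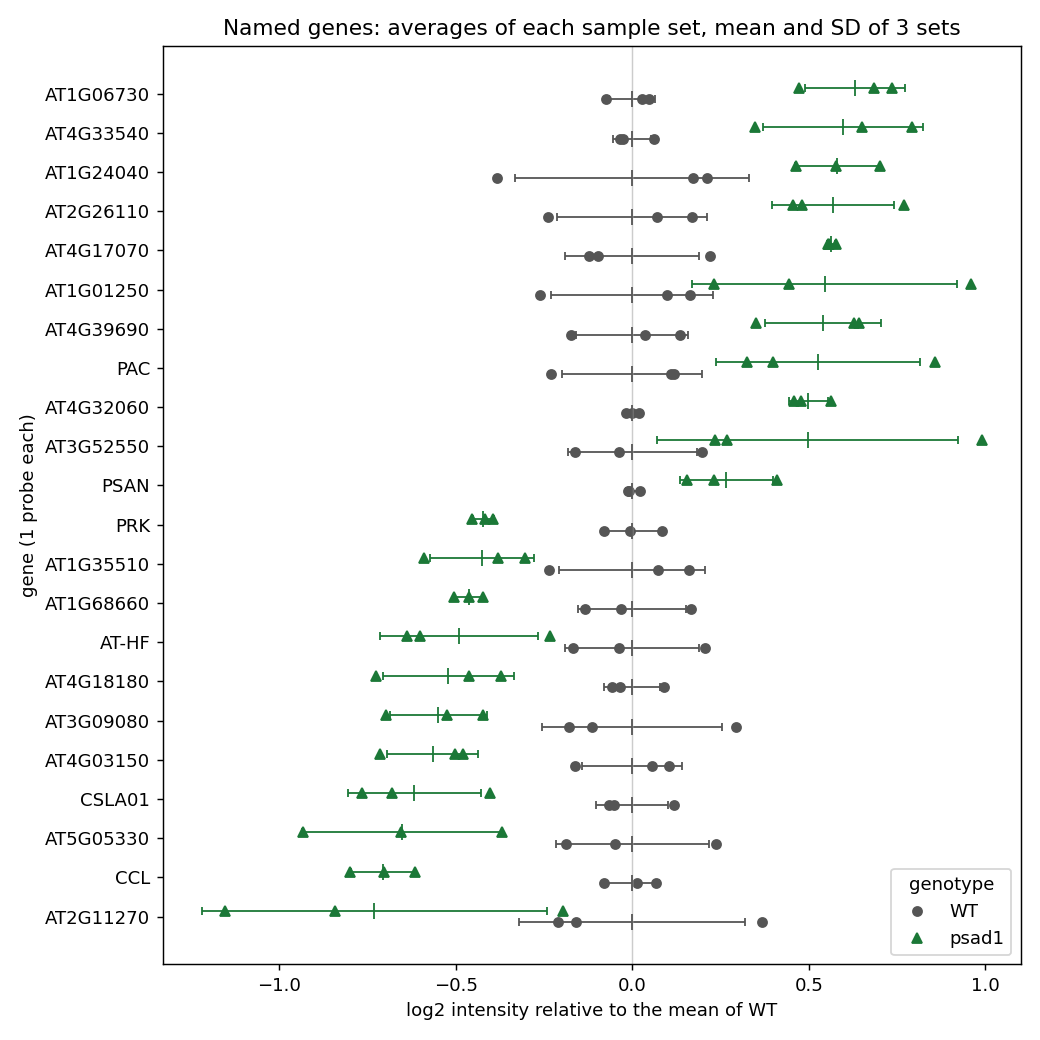
Log2 intensity relative to the WT mean for the 20 named changes and for PSAN and PRK, 1 probe per gene. Each point is the average of a set of 2 samples (grey circles WT, green triangles psad1), with the mean and SD over 3 sets. CCL lies at −0.71 and AT1G06730 at 0.63, each picked from these same data and with no overlap between the genotypes.

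Across the array, 505 of 3202 probes passed an adjusted p of 0.05 on 12 samples, 247 higher and 258 lower in psad1. On set averages 28 passed, 15 higher and 13 lower, all 28 among the 505, and with a set left out this count ranged from 9 to 53. Of those 28, 21 had no gene listed, 4 listed several genes and 3 were those of CCL, AT1G06730 and AT4G32060. Of the 640 tested probes with 1 gene, 91 passed on 12 samples (42 higher and 49 lower) and 3 on set averages. The changes were small: 46 probes differed by over 1.5-fold and 6 by over 2-fold, and the 5th and 95th percentiles of the log2 change were −0.29 and 0.38. Among probes with no gene listed that passed on set averages, those with the widest changes were picked after their values were seen. Probe 2235 was 2.29-fold higher (6.32 ± 1.46 against 2.71 ± 0.228) and probe 1701 2.26-fold higher in psad1, while probe 2464 was 2.16-fold lower. Set averages did not overlap between genotypes for 666 probes (20.8%), where 10% is the average to be met by chance over all splits of the sets. Neighbouring probes shared set differences, so a single split can lie away from 10%. The share in other splits was not computed, and no excess over chance is read from it.

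Log2 changes also depended on where a probe stood in the array's numbering, which was assumed to follow its layout. After subtraction of a running median over probe numbers, 7 of the 20 named genes passed on set averages: CCL, AT1G06730 and AT4G32060, joined by AT4G17070, AT4G39690, CSLA01 and AT4G03150. The log2 change shrank by over 1.5 times in AT4G33540 (0.36), AT2G26110 (0.27), AT1G01250 (0.23) and AT3G52550 (0.24). AT3G52550 (adjusted p 0.094) and AT2G11270 (0.0629) then missed the threshold on 12 samples too.

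**Figure D3:**
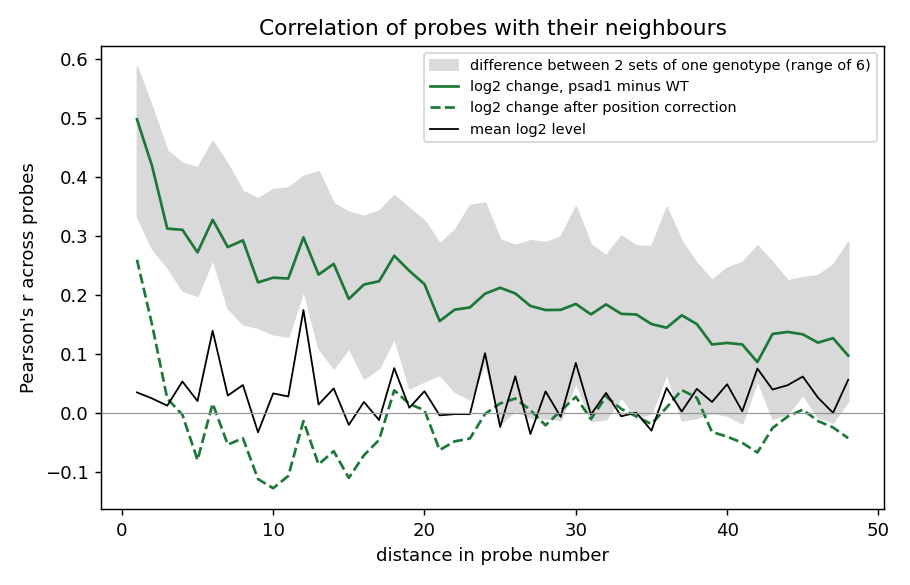
Pearson's r across probes between a value and that of the probe a given distance away in probe number. The log2 change of psad1 against WT (solid green) starts at 0.497, within the range of differences between sets of one genotype (grey), while the mean log2 level (black) starts at 0.0349.

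Few genes of photosynthesis could be traced to a tested probe that lists 1 gene. Others may lie among the 1877 probes not listed or the 870 with several genes. They count here as not identified, not as absent from the array. Of 338 genes in 22 lists, 17 were measured in this sense, in 8 lists, and PRK alone passed the test. PRK, phosphoribulokinase of the Calvin cycle and named because it passed, fell from 0.822 ± 0.0476 (SD, n = 3) to 0.614 ± 0.0119, a log2 change of −0.42 (SE 0.10). Its adjusted p was 0.000373 on 12 samples, 0.0797 on set averages and 0.0393 on set averages after the position correction. Among the 17 genes, 11 had higher and 6 lower values in psad1. The other Calvin cycle gene, SBPASE, measured 0.72 ± 0.0671 in WT and 0.721 ± 0.0738 in psad1. Adjusted over the list alone, 1 of these 2 genes fell, PRK, with 12 samples as with set averages.

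Photosystem I was represented by PSAN (AT5G64040), a small subunit on the lumen side, near the site where plastocyanin docks. PSAN measured 5.64 ± 0.501 in psad1 and 4.64 ± 0.0608 in WT, a log2 change of 0.27 (SE 0.11) that did not pass on 12 samples (adjusted p 0.0641) or on set averages (0.294). After the position correction it was 0.31, which passed on 12 samples (0.0375) and not on set averages (0.125). Adjusted over the list alone, which holds PSAN as its only measured gene, it passed in both. The repeats of psad1 set 1 differed, with 6.8 in sample 1 and 4.35 in sample 2, the latter below all WT samples (4.54 to 4.8). The 3 photosystem II genes did not pass, nor did they when adjusted over the list alone: PSBW had a log2 change of −0.19 (SE 0.13), PSBY of 0.09 (SE 0.13) and PSB27 of 0.04 (SE 0.15). That list's median was 0.04 and its mean −0.02, of opposite sign. Camera, which leaned downward, gave an adjusted p of 0.921 on 12 samples (0.922 with an estimated correlation) and 0.907 on set averages. The antenna gene LHB1B2 of light harvesting complex II was at 18.7 ± 3.15 in psad1 and 19.2 ± 1.73 in WT, and did not pass over all probes or adjusted over the list alone. After the position correction PSBW, PSBY and PSB27 had log2 changes of −0.17, −0.14 and −0.21, a mean of −0.18, and did not pass (camera adjusted p 0.139 on 12 samples and 0.163 on set averages). With the sample number as a block in limma, PSBW passed on 12 samples (adjusted p 0.0356), but not on set averages with the set number as a block (0.351).

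Of 5 genes for plastid ribosomal proteins none passed, adjusted over all probes or adjusted over the list alone. AT1G29070 had a log2 change of −0.40 (SE 0.14), with 2 psad1 samples at the floor, and AT3G54210, AT1G64510, AT4G01310 and AT3G13120 had 0.18, 0.11, 0.10 and 0.10. The list's median was 0.10 and its mean 0.02. Camera gave an adjusted p of 0.691 on 12 samples (0.874 with an estimated correlation) and 0.907 on set averages. With the sample number as a block in limma, AT1G29070 passed on 12 samples (adjusted p 0.0188), but not on set averages with the set number as a block (0.146). Of tetrapyrrole synthesis, the magnesium protoporphyrin methyltransferase gene CHLM had a log2 change of 0.21 and the geranylgeranyl reductase gene AT1G74470 one of −0.15, and neither passed, over the list alone included. Of oxidative and light stress, the thioredoxin reductase gene NTRC had 0.21 and the chloroplast peroxiredoxin gene AT3G52960 0.34. Neither passed over all probes, and AT3G52960 passed when adjusted over the list alone on 12 samples but not on set averages. Its log2 change was 0.05 after the position correction, and its higher values lay in psad1 samples 5 and 6 (1.76 and 1.73), against 1.1 to 1.2 in the other psad1 samples. The thioesterase gene FATB of fatty acid synthesis had −0.02 and did not pass. The position correction moved others that did not pass as well, to 0.04 for CHLM, 0.07 for NTRC, 0.01 for AT4G01310, −0.02 for AT3G54210, −0.16 for FATB, −0.10 for SBPASE and 0.04 for LHB1B2, none past the threshold.

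Neither PSAD1, the gene disrupted in the mutant, nor PSAD2, the other gene for PSI-D, was among the genes listed for any probe. Their transcripts were not analysed here, and the genotype labels were taken as given. The 14 lists with no measured gene covered light harvesting complex I, electron transport and ATP synthase, photorespiration, plastid chaperones and proteases, plastid protein import, starch and sugar transport, isoprenoids and carotenoids, aromatic amino acids, sigma factors and plastid RNA polymerase, non-green tissue markers, senescence, seed storage, pathogen response and reference genes.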

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

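Of 62 values examined for a sample lying far from the other samples of its genotype, 1 stood out. Chance alone marks about 1 in 20 where samples are independent, which these were not. The mean intensity of WT sample 5 was 1.07, against 1.05 to 1.06 in the other WT samples. Its gap to the nearest of them was 0.708 of the range in WT. None of the named genes had such a sample, but a set of 2 similar samples that lies apart is not marked in this way. AT3G52550, for example, was not marked, though psad1 samples 5 and 6 had 0.72 and 0.707, against 0.411 to 0.457 in the other psad1 samples.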

How the results depend on the processing

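The position correction, its combination with set averages, the common floor, set averages with a set left out or with the set number as a block were chosen after the data were seen. The numbers were not taken to pair the samples, since not every pair exceeded 0.1: deviations of same-numbered samples of both genotypes correlated between 0.00805 and 0.483, 4 of 6 over 0.1, and 8 of 12 samples correlated best with their own number. With the replicate block 761 probes passed, PSBW (adjusted p 0.0356) and AT1G29070 (0.0188) passed and AT1G01250 (0.0533) did not, and set averages with the set number as a replicate block gave 27, with PSBW at 0.351 and AT1G29070 at 0.146. Against 505 on 12 samples, 84 passed with sets as a random block, 28 on set averages and 59 on set averages after position correction. Thresholds of 0.01 and of 1.5-fold left 223 and 45. Set averages without WT set 1, 2 or 3 gave 11, 14 and 17, and without psad1 set 1, 2 or 3 gave 14, 9 and 53. The counts from the remaining alternatives lay within 1.5 times of 505, from 377 with the Welch test to 630 with quantile normalization, and leaving out 1 sample gave 387 to 553. Of probes that passed on 12 samples 48.9% were higher in psad1, against 41.1% with the replicate block and 57.2% after position correction. On set averages 53.6% were higher, against 37% with the set number as a block and 52.9% to 77.8% with a set left out.

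None of the 20 named changes that passed turned direction in any alternative, and 19 passed whichever sample was left out, which keeps its repeat in the fit. On set averages with a set left out, 0 of the 20 passed without WT set 1, WT set 2 or psad1 set 2, 1 (CCL) without WT set 3 or psad1 set 1, and 5 without psad1 set 3. AT3G52550 passed in 6 of 12, not without WT sample 3, 4, 5 or 6 or psad1 sample 5 or 6 (highest adjusted p 0.0638). Neither tested list passed in any alternative on 12 samples. On set averages fry's mixed test, run for lists only, gave 0.0388 for plastid ribosomal proteins.

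Changes of sign, with no cause tested, met only values that had not passed. The photosystem II mean became 0.0083 with quantile normalization, 0.0069 without psad1 sample 3 (range −0.047 to 0.0069 over left-out samples) and 0.026 on set averages without psad1 set 2, while its widest move, with no change of sign, was to −0.18 after position correction. PSB27 became −0.030 and −0.033 without psad1 samples 1 and 2 (up to 0.12 without others), −0.0030 and −0.13 on set averages without WT set 1 and psad1 set 1, and −0.21 after position correction. PSBY became −0.14 after position correction and −0.024 without WT set 3, and AT3G54210 −0.022 after position correction. The plastid ribosomal mean became −0.030 after position correction, −0.021, −0.0061 and −0.0027 without psad1 samples 3 and 5 and WT sample 6 (up to 0.048 without others), and −0.021 and −0.0052 on set averages without psad1 sets 2 and 3. The offset gave AT3G52550 0.33. Signal near the floor limits AT5G05330, AT4G03150, CSLA01 and AT1G29070. AT1G06730 (0.424 in WT) and PAC (0.418) were as dim as CSLA01 (0.45). Their log2 changes ranged over all alternatives from 0.43 to 0.78 and from 0.36 to 0.63.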

Other observations

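The splits of the sets, the fit without a trend in intensity, the count of probes left after the position correction, the correlation of levels and the 7 gene lists below were chosen only after the data were seen. These 7 lists were drawn up from the symbols of probes with 1 gene, and none passed camera on 12 samples, on set averages or after position correction of set averages. The chloroplast NDH complex, which carries electrons around photosystem I, was represented by NdhS, which rose from 6.24 ± 0.203 (SD, n = 3) in WT to 7.81 ± 0.598 in psad1, by 0.32 on the log2 scale (limma adjusted p 0.00327 on 12 samples and 0.199 on set averages). NdhN had a log2 change of −0.13 and did not pass. NdhS alone passed among 11 measured genes for photosystem and NDH subunits and assembly (camera adjusted p 0.793).

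Among 5 genes of tetrapyrrole and carotenoid synthesis, HEMA3, a glutamyl-tRNA reductase gene, rose by 0.37 (adjusted p 0.0188 and 0.249), but its log2 change was 0.06 after position correction (camera adjusted p 0.26 for the list). Among 6 genes for organelle RNA or DNA factors, called organelle RNA factors below, PAC rose. AT5G55580, CRR21, OTP70, OSB1 and OTP85 had log2 changes of 0.26, 0.24, 0.19, −0.02 and −0.04 and did not pass. For this list camera gave p 0.0524, adjusted p 0.26, and 0.317 with an estimated correlation. Adjusted over the list alone, 2 members rose on 12 samples, PAC and AT5G55580, and 1 on set averages. After position correction AT5G55580 had 0.26, which passed on 12 samples (adjusted p 0.00651) and not on set averages (0.123). Among 5 genes of carbon metabolism PRK fell, and SBPASE, PPDK, ATSPS4F and AT5G58330 had 0.0003, −0.06, −0.03 and −0.09 and did not pass (camera adjusted p 0.26). None of 7 genes for redox and detoxification passed. AT3G52960, NTRC, GLX2-1, CHL and CCS were at 0.34, 0.21, 0.14, 0.14 and 0.10, and SRX and GLDH at −0.03 and −0.05 (list median 0.14, camera adjusted p 0.349). Of 7 flower and meristem regulators, chosen as markers of other tissues, AGL26 fell by 0.21 (0.0361 and 0.342), and SPL had −0.12 and did not pass (list adjusted p 0.723). Of 5 cell wall enzymes CSLA01 fell, and the cellulase genes GH9B11 and GH9B8 had 0.19 and 0.29 and did not pass (list adjusted p 0.802). After position correction CRR21 had 0.04, GH9B8 0.07, GH9B11 0.10, NdhN −0.04, SPL −0.02, OTP85 0.07 and SRX 0.03, none past the threshold. Members that passed did so on 12 samples and not on set averages, and of them PRK (0.0393) and CSLA01 (0.042) passed on set averages after position correction. Fry tests whether members move one way on balance. It sets them against no change at all, where camera sets them against the other probes, so a single changed member can suffice. Fry gave adjusted p 0.000342 for carbon metabolism, 0.0202 for tetrapyrroles and carotenoids and 0.0202 for organelle RNA factors on 12 samples, and 0.0744, 0.219 and 0.219 on set averages. After position correction of set averages it gave 0.019, 0.537 and 0.0146, and 0.019 for flower and meristem regulators. Its mixed test, for changes either way, passed on 12 samples for photosystem and NDH subunits (0.00135) and carbon metabolism (0.00796), and on set averages for carbon metabolism alone (0.00333, against 0.139 for photosystem and NDH subunits). After position correction of set averages it passed for these lists (0.00758 and 0.00773), organelle RNA factors (0.00773) and flower and meristem regulators (0.0227).

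A first pattern is the gap between 505 probes past the threshold on 12 samples and 28 on set averages. In 100 splits of the 12 samples, 1, the real one, gave as many as 505, the highest other giving 7, but 98 of the 99 others parted at least 1 set, so this count does not settle whether differences between sets reach 505 by chance. The 6 sets allow 10 splits, too few for a share under 0.05: 1 of them gave 28, the real one, and the highest other gave 0. The other splits of whole sets gave 0, 0, 0, 1, 7, 27, 72, 227 and 236 on 12 samples. The highest may reflect differences between sets, but each of these splits held the genotypes unequally, so part of any genotype difference enters too. In simulated data with the measured set structure 39.5% of calls on 12 samples were false (123 of 311, with 200 probes changed), and with no changed probe 50 were called on 12 samples and 0 on set averages. Part of the 505 may thus be repeat samples counted as replicates. The simulated counts lie below 505 but do not bound that part. Set differences were simulated separately for each probe, whereas in the data those of neighbouring probes correlated (r 0.333 to 0.586). As a hypothesis, the 28 are the firmer list. An effect of genotype stays open for both.

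A second pattern is that log2 changes of neighbouring probe numbers resembled each other, with r 0.497 across 2229 neighbour pairs. A trend with the measured intensity is argued against: intensities of neighbours correlated by 0.0349 (at most 0.174, at a distance of 12), and r was 0.495 once any trend of the log2 change with intensity was removed. An effect of array position that differs between the genotypes' samples may be part of it: among neighbours both among the dimmest 25% of probes r was 0.636 (95% interval 0.532 to 0.727), against 0.308 (0.15 to 0.462) among the brightest 25%. Set-to-set differences within a genotype gave 0.44 of the observed autocovariance (0.392 to 0.495), or 0.497 with sets paired by number (0.413 to 0.588). The bound set beforehand against such differences, an interval below 0.5, was met by the first value; the second was made to count as well only after both were seen. The intervals leave out the draw of only 3 sets per genotype, so such differences cannot be told apart from an effect of genotype. A trend over 25 probe numbers as the whole cause of the calls on set averages is argued against, since 25 of the 28 remained past the threshold after it was subtracted. Log2 changes of neighbours still correlated by 0.259 then, so position effects over shorter distances stay open, and probe number as the order on the array is an assumption.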
